A study of Mus musculus with 4 samples.

How the data were processed

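The series measured RNA from sorted mouse spleen cells on 4 single-colour Illumina arrays: 1 of naive follicular B cells, 1 of Blimp1-hi plasma cells and 2 of Blimp1-int plasma cells. Per the labels' protocols, RNA was extracted with Trizol and a column kit with DNase treatment and amplified to labelled cRNA with a MessageAmp kit. The values used are the deposited processed values on a log2 scale, made by the authors with the R package lumi per the submitters' processing notes, which give no version. All 4 arrays hold nearly the same sorted values, with a median of 8.36 on each and a maximum of 16.03, as quantile normalization leaves them. Whether the deposited log2 scale is a plain log2 or a variance-stabilized one is not given in the sources used here, nor is the background step. On a variance-stabilized scale a difference of 1 near background is more than 2-fold, and folds of dim genes are then understated. A deposited table of raw signals holds 8 columns of values, 4 of them signals and 4 detection p-values. Its column names match no sample, so none of these was used. The design fixed before the data were examined allowed for this case. The planned filter on detection p-values was replaced by a background cutoff, the mean plus 3 standard deviations, per array, of 43 probes for sequences foreign to the mouse (bacterial, plant, spike-in and vector), which lay between 8.65 and 8.69. The levels of Ighg3, Ighg2c, Igkc and Ighm on the plasma cell arrays lie near the top of the scale, where differences between arrays are compressed.

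The array's probe identifiers carry no gene symbols. The zero-padded numbers in 11897 identifiers were matched as NCBI gene numbers to a table of mouse RefSeq genes (assembly GRCm38.p6, used for names only), and 9832 were found. Of the 5-digit numbers 84.3% matched, against 50.9% after a shift by 7 and 44.3% after a shift by 50, and of the 6-digit numbers 79.7% against 23.8% and 19.1%. Pairs of probes with the same number, 167 above background, correlated across pairs in their plasma cell minus naive difference with r = 0.566, against at most 0.341 in 1000 shuffles. A further 9 probes were named by a RefSeq accession and 9 by an immunoglobulin constant region in the identifier. In all 9850 probes have 1 symbol, for 8137 genes, and 36270 have none here; genes such as Mcl1, Prdm1 and Tnfrsf17 are therefore not analysed here. Probes of immunoglobulin variable segments (289), mitochondrial transcripts (13), 18S ribosomal RNA, eGFP and the neomycin resistance gene are named by their identifiers and were kept apart from the gene tests. Near-identical gene copies cannot be told apart by a probe.

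For each gene the probe with the highest mean among those above background on at least 1 array was used. A linear model with 3 groups was fitted to all 4 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), two-sided. Its 1 residual degree of freedom is the Blimp1-int pair, moderated across genes (prior 11.6 degrees of freedom, prior standard deviation 0.0878). No source says that the Blimp1-int arrays came from separate animals, so p-values measure only the spread between these 2 samples, which may be technical. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1 (2-fold). Every gene past 2-fold also passed the test, so the fold threshold sets the calls. A gene below background on every array of 1 group has only a bound: the brighter group's mean over the dim group's mean of, per array, the higher of the lowest signal above background and the probe's own value, written as at least N-fold. For genes that were not called, the deposited difference is given, and it is not exact where a group lies below background.

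Gene lists (29) were fixed before the data were examined. For lists with at least 4 tested members, camera was run with a preset inter-gene correlation of 0.01 and with an estimated one. The estimated correlation rests on 1 residual degree of freedom here, so that test has almost no power and a list failing it decides nothing. Each list's median was also ranked among 10000 random lists of the same size matched on mean expression. The genes named are all measured BCL-2 family, BAFF and APRIL genes and the sort markers; per comparison the 10 called genes per direction with the largest difference among those above background on every array of both groups, with both Blimp1-int replicates on the same side; the 5 per direction with the largest bound among genes below background in the lower group; and from each other list up to 4 called members, or up to 2 uncalled ones where none was called. Gene models and clone names were left out, and an item that the rule would name is not reported here. Other gene names, probe classes and ribosomal RNA were chosen after their values were seen.

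The steps were tested on simulated data. With 200 of 2625 genes changed by known amounts, on values drawn with the pooled spread of the Blimp1-int pair (0.104), the call rule found 50 of 50 genes changed by 1.5 and 50 of 50 changed by 2 on the log2 scale in each of the 3 comparisons, 0 of 50 changed by 0.5, and 34, 23 and 29 of 50 changed by exactly 1 in Blimp1-hi versus naive, Blimp1-int versus naive and Blimp1-hi versus Blimp1-int. It called 0 of 2425 unchanged genes in each. These simulations assume that the single arrays vary like the Blimp1-int pair. A list shifted by 0.5 was the 1 list called of 17. The simulated genes were drawn independently, so this does not test the list calls where members vary together. Alternatives varied the scaling, filter, probe rule, moderation, arrays in the fit and thresholds; one, a quantile normalization after removing 309 immunoglobulin probes, was added after the data were seen. Figures were drawn with matplotlib 3.10.9.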

Results

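Gene expression was measured on 4 Illumina arrays in cells sorted from the spleen of C57BL/6 mice that carry a Blimp1-GFP reporter, in which green fluorescent protein marks cells that express Blimp1, the transcription factor of plasma cell differentiation. The naive follicular B cells were sorted as B220+ IgD+ cells and fill 1 array. Plasma cells were sorted as CD138+ cells and split by reporter level into a Blimp1-high population (Blimp1-hi, 1 array) and a Blimp1-intermediate population (Blimp1-int, 2 arrays). The source field of these 3 arrays names B cells of the follicle instead, in conflict with their titles and sort description, which the grouping follows. The plasma cells came from pools of 5 to 10 animals. Between 6286 and 6960 of the 46120 probes exceeded the background level on each array. A gene name was available for 9850 probes, and 2625 named genes exceeded background on at least 1 array and were tested. The number of arrays limits the tests: the naive and Blimp1-hi groups have no replicates, and their arrays are assumed to vary like the Blimp1-int pair. The p-values hold no measure of the variation between naive or between Blimp1-hi samples. Levels below are the deposited values on a log2 scale, errors of differences are standard errors (SE) from limma, and p-values are limma's after Benjamini-Hochberg adjustment. A gene is called higher or lower where the adjusted p is under 0.05 and the difference is at least 1 on the log2 scale, which is 2-fold.

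The sort labels were checked on the reporter and on the surface marker first. The eGFP probe lay at 8.29 in naive B cells, 11.23 in Blimp1-hi, and 10.55 and 10.82 in the Blimp1-int replicates. A second reporter probe, GFP, was below background on all arrays (8.51 in naive cells, 8.36 in Blimp1-hi, 8.32 and 8.28 in Blimp1-int) and so shows no order. The naive level was below background, so that eGFP was at least 6.00-fold higher in Blimp1-hi and at least 4.10-fold higher in Blimp1-int than in naive cells, with adjusted p = 5.89e-05 and 5.87e-05 in the limma fit over all probes. The order of the plasma cell populations, Blimp1-hi above Blimp1-int by 0.55, did not pass that test (adjusted p = 0.0723). Sdc1, which encodes CD138, rose from below background in naive B cells (8.24) to 9.55 in Blimp1-hi and to 9.21 and 9.36 in Blimp1-int. Sdc1 was at least 1.87-fold higher in Blimp1-hi and at least 1.55-fold higher in Blimp1-int than in naive cells (adjusted p = 2.34e-06 and 3.76e-06). Ptprc, whose B220 isoform was used to sort the naive cells, lay near background on all arrays (8.52 to 8.71), so that its probe says nothing about the sort. Prdm1, the gene of Blimp1 itself, has no named probe and was not analysed here. Across all probes the Blimp1-int replicates correlated with r = 0.984, Blimp1-hi correlated with them with r = 0.965 and 0.970, and the naive array correlated with the plasma cell arrays with r between 0.797 and 0.830 (across probes, which are not independent replicates).

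The first comparison asked how Blimp1-hi plasma cells differ from naive follicular B cells. In Blimp1-hi 8 of 10 tested immunoglobulin genes and 9 of 18 secretory genes were called higher, and 4 of 8 B cell transcription factors, 4 of 7 B cell surface genes and 5 of 5 MHC class II genes lower. As lists, all 5 passed a test with a preset correlation and none with an estimated one (adjusted p = 0.547, and adjusted p = 0.603 for MHC class II, with an estimated correlation). Of 2625 genes, 118 were called higher and 203 lower, of which 90 and 173 lay above background on both arrays. The other calls rest on a value below background, and their bound can lie under 2-fold. The highest rises among genes measured on both sides were Ighg3, from 9.97 to 15.71 (log2 difference 5.74, SE 0.13, adjusted p = 3.7e-12), and Ighg2c, from 9.85 to 15.40 (5.55, SE 0.12). These are constant regions of IgG subclasses whose sequences are similar enough that a probe can bind more than 1 of them, and their plasma cell levels lie near the top of the scale, where differences are compressed. Next came Xbp1, the transcription factor that drives the secretory program of plasma cells (3.74, SE 0.12), and Txndc5, an endoplasmic reticulum (ER) disulfide isomerase (3.56, SE 0.18). Reln rose by 2.78, Ctsb, the lysosomal protease cathepsin B, by 2.70, and Mtdh by 2.54. Among genes below background in naive cells, Chst1, a sulfotransferase of the Golgi, was at least 16.8-fold higher, Igha, the constant region of IgA, at least 12.9-fold, Tmed10 at least 9.26-fold, and the kappa variable segment Igkv1-110 at least 8.79-fold higher in Blimp1-hi. In the opposite direction, Spib, an Ets transcription factor of B cells, was at least 19.2-fold lower and the inhibitory receptor Cd72 at least 11.7-fold lower. H2-DMb2, a chaperone of MHC class II peptide loading, fell by 3.78 (SE 0.13), as did Klf2, a transcription factor of quiescent and recirculating lymphocytes (-3.21). The other large falls were those of Snn (-3.46), the Fc receptor homologue Fcrl1 (-3.10), Rcsd1 (-2.97), Lmo2 (-2.97), Srpk3 (-2.96), the kinase gene Mknk2 (-2.92) and Klhl6 (-2.89). Cnn3, Rasgrp1 and Ripor2 were at least 6.24-fold, 6.12-fold and 5.97-fold lower, below background in Blimp1-hi.

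**Figure D1:**
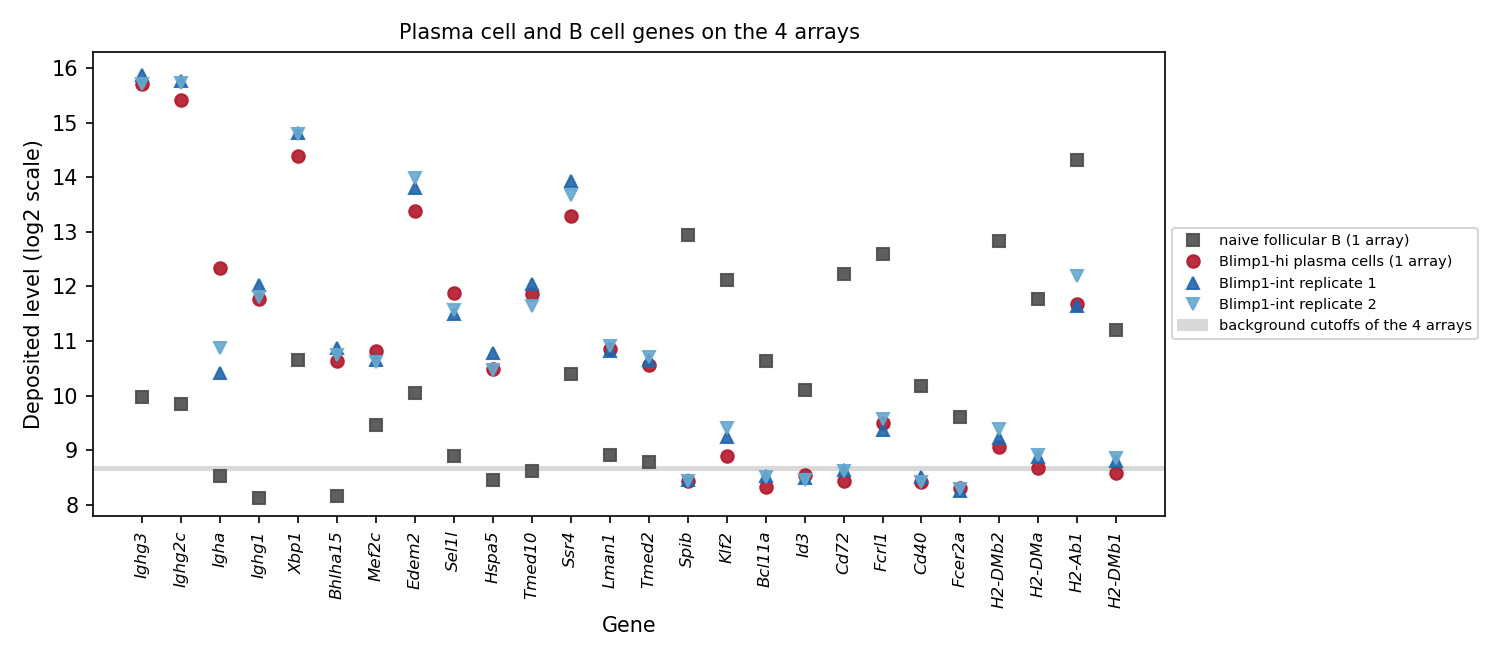
Deposited levels on the log2 scale (vertical axis) of genes from the immunoglobulin, plasma cell transcription factor, unfolded protein response, secretory, B cell transcription factor, B cell surface and MHC class II lists (horizontal axis); each symbol is 1 array and the grey band spans the background cutoffs of the arrays. From Ighg3 to Tmed2 the plasma cell arrays lie above the naive array, and from Spib to H2-DMb1 they lie below it, many of them within or under the band.

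Gene lists fixed before the data were examined describe the same contrast by function. Of 10 tested immunoglobulin genes, 8 were called higher in Blimp1-hi and 2 were not called; by adjusted p alone 9 were higher. The ER translocon and secretory machinery list had 9 of 18 tested members called higher and no member lower, including the translocon-associated subunit Ssr4 (2.89, SE 0.14), the cargo receptor Lman1 (1.94, SE 0.12) and the transport vesicle protein Tmed2 (1.78, SE 0.12). Of 4 tested unfolded protein response genes, 3 rose: Edem2 (3.33, SE 0.13) and Sel1l (2.98, SE 0.12), both of ER-associated degradation, and the ER chaperone Hspa5, which was at least 3.60-fold higher. Of 5 tested plasma cell transcription factors, Xbp1, Bhlha15 and Mef2c rose, Bhlha15 by at least 3.96-fold and Mef2c by 1.35 (SE 0.12). All 5 tested MHC class II genes fell, with H2-Ab1, the beta chain of I-A, going from 14.32 to 11.69 and H2-DMa falling by 3.09, and H2-DMb1 being at least 5.75-fold lower. Of 8 tested B cell transcription factors 4 fell, Spib, Klf2, Bcl11a (at least 3.87-fold) and Id3 (at least 2.68-fold). Of 7 tested B cell surface and receptor signalling genes 4 fell, Cd72, Fcrl1, the costimulatory receptor Cd40 (at least 2.83-fold) and Fcer2a, which encodes CD23 (at least 1.92-fold). In all lists and comparisons, the counts of calls adjusted over the list alone equalled those over all genes. limma's camera test with a preset inter-gene correlation of 0.01 gave adjusted p = 1.93e-09 for the immunoglobulin and for the secretory list, 0.000233 for the unfolded protein response, 7.68e-05 for plasma cell transcription factors, 4.95e-05 for MHC class II, 2.67e-05 for B cell transcription factors and 0.000756 for B cell surface genes. None of these list calls held with an estimated correlation, which has 1 residual degree of freedom here: the adjusted p was then 0.547 for each of them except MHC class II, where the adjusted p was 0.603 with the estimated correlation. The medians of the immunoglobulin, secretory and unfolded protein response lists lay above all of 10000 random lists matched on mean expression (percentile 100). Those of both B cell lists lay below all of them (percentile 0). Random lists draw genes independently, so these ranks take no account of members that vary together and measure no spread between samples. These ranks do not replace a test of the lists across samples. With 1 residual degree of freedom, the test with an estimated correlation has almost no power. Its unadjusted camera p for the secretory list was 0.0904, against 1.16e-10 with the preset correlation. That it did not pass says nothing for or against a list.

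Transcripts of cytosolic ribosomal proteins were mostly lower in Blimp1-hi than in naive B cells. Of 30 tested members 17 fell, 2 rose (Rpl6 by 1.24 and Rps6 by 1.11) and 11 were not called (by adjusted p alone 22 fell and 4 rose), with a median difference of -1.02 (adjusted p = 1.22e-05 by camera, adjusted p = 0.691 with an estimated correlation). The largest falls were those of Rps15 (-2.54), Rpl13 (-2.48), Rps9 (-2.18, over 1.5 times smaller with the mean of its probes) and Rps16 (-1.99), with SE of 0.12 to 0.13. When the array values were normalized again without the immunoglobulin probes, an alternative chosen after the data were seen, the median of this list was -0.40 and 136 genes were called higher and 133 lower in Blimp1-hi, against 118 and 203. Of 23 tested oxidative phosphorylation genes 4 fell, namely Uqcrh (-2.05), Cox6b1 (-1.30), Ndufa2 (-1.09) and Atp5h (-1.02), and 19 were not called (by adjusted p alone 10 fell and 5 rose); the calls of Cox6b1, Ndufa2 and Atp5h ended under that renormalization. Of 9 tested glycolysis genes, Gapdh (-1.28), Ldha (-1.27) and Eno1 (-1.04) fell, of which the calls of Gapdh and Eno1 also ended under it. Those of Eno1 and Atp5h ended under 75th percentile scaling too, and that of Eno1 under cyclic loess. As lists, neither oxidative phosphorylation (camera adjusted p = 0.471) nor glycolysis (0.135) passed camera. The glycolysis median of -0.85 lay at percentile 2.42 of matched random lists, outside the central 95%, and the list passed camera with no filter (adjusted p = 0.0113). Ribosomal RNA and mitochondrially encoded transcripts also differed between the same arrays: the 3 probes of 18S ribosomal RNA were higher in Blimp1-hi than in naive cells by 2.62 to 3.92, and the mitochondrially encoded probes COXIII, ND4, ND1, COXI and ND5 were lower, with differences of -1.68, -1.51, -1.80, -1.05 and -1.13. ND4L, below background in naive cells, was at least 1.82-fold higher (adjusted p = 0.00547).

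None of 14 tested cell cycle genes was called in Blimp1-hi (median 0.10, Mcm7 -0.77, Cenpa -0.74). Klf2, the only called member of 3 tested migration genes, is given above. Cd40 and the kinase gene Map3k14 (-1.03, a call that ended under 75th percentile scaling and without the immunoglobulin probes) were the called members of 3 tested NF-kB genes, and the autophagosome gene Map1lc3b rose by 1.46. No member was called among 4 N-glycosylation genes (Uggt1 0.47, Ganab 0.35), 3 amino acid genes (Aars 0.95, Phgdh 0.75), 3 cell cycle inhibitor and p53 target genes (Btg1 -0.32, Ccng1 0.29), 5 interferon-stimulated genes (Irf9 -0.51, Oas1a -0.36), 4 immediate early and stress genes (Klf6 0.95, Hsp90aa1 0.72) or 7 cholesterol synthesis genes (Hmgcs1 -0.80, Fdps 0.77). Phgdh, Ccng1 and Hsp90aa1 were below background in naive cells and Btg1 and Oas1a in Blimp1-hi, so that their differences are not exact. Aars and Klf6 gained a call under 75th percentile scaling (both 1.02) and without the immunoglobulin probes (1.08 and 1.03). The immediate early list passed camera with a median of 0.59 (adjusted p = 0.0236, and adjusted p = 0.581 with an estimated correlation), a call that ended under 75th percentile scaling (0.0541) and cyclic loess (0.0767). Markers of other spleen cells could be checked only in small part. Of 20 T and NK cell markers 3 had a named probe, and of 18 granulocyte markers 7. None of these exceeded background on any array. Of 19 macrophage, 20 erythroid and 14 stromal and endothelial markers, 2, 1 and 1 were tested, and none was called. The erythroid gene Hba-a1 differed by -0.50, the endothelial gene Pecam1 by -0.86, and the macrophage genes Apoe and Vcam1 by 0.70 and 0.11. Hba-a1 was below background in Blimp1-hi and Vcam1 in both groups, so that their differences are not exact.

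The second comparison set Blimp1-int plasma cells against the same naive array. In Blimp1-int 12 of 18 tested secretory genes and 3 of 14 cell cycle genes were called higher, and 5 of 8 B cell transcription factors lower; none of these lists passed with an estimated correlation (adjusted p = 0.56, 0.649 and 0.56). Of 2625 genes, 157 were called higher and 152 lower, of which 125 and 124 lay above background on every array of both groups. Both Blimp1-int replicates lay on the same side of the naive value for all 309. Ighg2c rose by 5.89 (SE 0.10, adjusted p = 3.92e-13) and Ighg3 by 5.82, both to near the top of the scale, so that their order is uncertain. Xbp1 rose by 4.15, Edem2 by 3.85, Ssr4 by 3.40, Txndc5 by 3.31, Mtdh by 2.88, Ctsb by 2.64 and Sel1l by 2.63. The replication-dependent histone gene H2ac10 rose by 2.56 (SE 0.16); its family has near-identical copies, and the probe cannot be assigned to 1 of them with certainty. From below background in naive cells, Chst1 was at least 12.2-fold higher, Ighg1 at least 9.65-fold, Tmed10 at least 9.22-fold, Tent5c, a poly(A) polymerase, at least 7.46-fold, and Bhlha15 at least 4.50-fold higher. Snn fell from 13.25 to 8.95 and 9.54, and large falls were also seen for H2-DMb2 (-3.53), Fcrl1 (-3.12), Arhgef3 (-3.06), Rcsd1 (-2.95), Gga2 (-2.92), H2-DMa (-2.88), Sbk1 (-2.82), Klhl6 (-2.80) and Klf2 (-2.79). Below background in Blimp1-int were Spib (at least 19.2-fold lower), Cd72 (at least 11.6-fold), Cnn3 (at least 6.21-fold), Bcl11a (at least 3.85-fold) and Rbm38 (at least 3.53-fold).

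In the lists, 8 of 10 tested immunoglobulin genes rose in Blimp1-int, among them Jchain, which links IgM and IgA multimers (at least 3.97-fold). Of 18 secretory genes 12 rose, including the translocon subunit Sec61g (2.05, SE 0.11) and Lman1 (1.94), as did 3 of 4 unfolded protein response genes (Hspa5 at least 3.95-fold) and 3 of 5 plasma cell transcription factors (Mef2c by 1.17). All 5 MHC class II genes fell (H2-Ab1 -2.41, H2-DMb1 -2.37), as did 5 of 8 B cell transcription factors (Id3 at least 2.67-fold) and 4 of 7 B cell surface genes (Cd40 at least 2.81-fold, Fcer2a at least 1.91-fold). Of 14 tested cell cycle genes, Mki67, the proliferation marker Ki-67, rose by 1.65 (SE 0.10), Cdc20, an activator of the anaphase-promoting complex, by 1.13, and the spindle gene Nusap1 by 1.03, and 11 were not called; by adjusted p alone 12 rose. Of these 3, Nusap1 was not called between the plasma cell populations. Probes of Cdc20 disagreed in size: the mean over its 2 probes above background gave 0.53. Of 30 ribosomal protein genes 8 fell (Rps15 -2.31, Rps9 -2.08, Rps16 -1.86, Rpl35 -1.63) and 2 rose; the call of Rps9 ended with the mean of its probes (-0.87), as did that of Fcer2a (-0.99). Pgk1 rose by 1.12 among 9 glycolysis genes, and Fdps by 1.43 and Nsdhl by 1.02 among 7 cholesterol synthesis genes. Uqcrh (-2.04) and Cox6b1 (-1.02) fell among 23 oxidative phosphorylation genes. The call of Cox6b1 ended under 75th percentile scaling (-0.99), with the mean of its probes (-0.65) and without the immunoglobulin probes (-0.71). Klf2 fell among 3 migration genes, Cd40 and Map3k14 (at least 2.03-fold) among 3 NF-kB genes, and Map1lc3b rose by 1.28 (its list had a median of -0.01, a mean of 0.17 and an upward camera direction that did not pass). No member was called among N-glycosylation (Uggt1 0.95, Ganab 0.62), amino acid (Phgdh 0.88, Aars 0.80), cell cycle inhibitor (Ccng1 0.58, Btg1 -0.37), interferon-stimulated (Oas1a -0.50) and immediate early genes (Klf6 0.92, Hsp90aa1 0.73), nor among the markers Vcam1 (0.37), Apoe (-0.35), Hba-a1 (-0.29) and Pecam1 (-0.92). Phgdh, Ccng1, Hsp90aa1 and Vcam1 were below background in naive cells, and Btg1, Oas1a and Hba-a1 in Blimp1-int, so that their differences are not exact. The 18S ribosomal RNA probes were higher in Blimp1-int than in naive cells by 2.23 to 3.78. By camera, 9 of 17 lists passed: the secretory (adjusted p = 1.13e-09), immunoglobulin (5.19e-07), B cell transcription factor (9.35e-06), MHC class II (6.56e-05), B cell surface (0.000142), cell cycle (0.0003), unfolded protein response (0.000481), plasma cell transcription factor (0.000544) and ribosomal protein lists (0.00194, a call that ended without the immunoglobulin probes). With an estimated correlation 0 of 17 passed, with adjusted p = 0.56 for the secretory, immunoglobulin, both B cell and the unfolded protein response lists, and adjusted p between 0.622 and 0.683 for the rest of the 9.

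Most differences from naive B cells were shared by the plasma cell populations. Called higher in both were 99 genes and called lower in both 139, and 0 were called in opposite directions. Both comparisons use the same naive array, which by itself makes their differences correlate. In 100 simulated sets with no effect and a shared naive array, at most 0 genes were called higher in both and 0 lower in both. These sets assume that the naive array varies like the Blimp1-int pair, so they do not cover a larger deviation of that array. Independent lists of these sizes would share 7.06 and 11.8 genes. The log2 differences correlated across genes with r = 0.94, against 0.575 in 100 simulated sets of unchanged groups with a shared naive array, and their covariance was 0.509 against 0.00795. With 1 naive array the control cannot be split, so part of the excess may come from it. Another 83 genes were called in Blimp1-hi alone and 71 in Blimp1-int alone, but of these only 3 and 9 were also called between the plasma cell populations themselves.

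**Figure D2:**
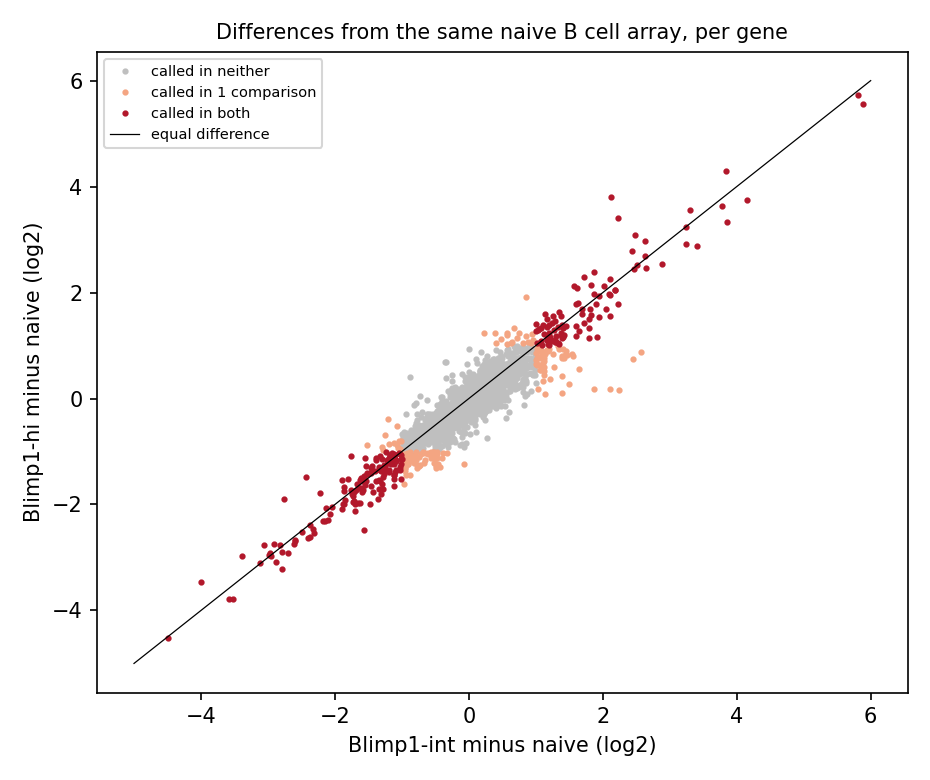
Difference from the naive array on the log2 scale for each of 2625 genes, Blimp1-int on the horizontal and Blimp1-hi on the vertical axis, with each point coloured by the comparisons in which the gene was called. Points lie along the line of equal difference; r = 0.94 across genes, and simulations with no effect and a shared naive array gave r = 0.575.

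The third comparison, between the plasma cell populations, asked what changes as the Blimp1 reporter goes from intermediate to high. Of 9 tested genes of the H2A histone family, a family picked out after the values were seen and not tested as a list, 6 were called lower in Blimp1-hi, as were 3 of 14 cell cycle genes. Igha was among the 7 named genes called higher, and of 197 variable segment probes, kept apart from these genes, 61 were called higher and 0 lower. Of 2625 genes, 7 were called higher and 11 lower, and in all 18 the Blimp1-hi value lay on the same side of both Blimp1-int replicates. The 11 lower genes hold 6 genes of the H2A histone family, H2ac24 (-2.08, SE 0.14), H2ac13 (-1.92), H2ac22 (-1.71), H2ac10 (-1.69), H2ac20 (-1.69) and H2ac12 (-1.22), whose near-identical sequences make them uncertain as separate genes. They also hold the kinetochore gene Spc24 (-1.28), the centromeric histone gene Cenpa (9.76 against 10.82 and 10.70), Anapc5, a subunit of the anaphase-promoting complex (-1.16), Mki67 (-1.09, SE 0.10, adjusted p = 4.11e-05) and Cdc20 (-1.05). The call of Cenpa ended under 75th percentile scaling, cyclic loess and the normalization without immunoglobulin probes, and that of Cdc20 with the mean of its probes (-0.41). Without Blimp1-int replicate 1 Cenpa and Cdc20 differed by -0.95 and -0.99, under 2-fold. Of 14 tested cell cycle genes 3 fell, 13 had a negative difference, and the median was -0.67 (camera adjusted p = 1.23e-08, adjusted p = 0.695 with an estimated correlation). That median lay below all of 10000 matched random lists (percentile 0), a rank that takes no account of members that vary together.

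**Figure D3:**
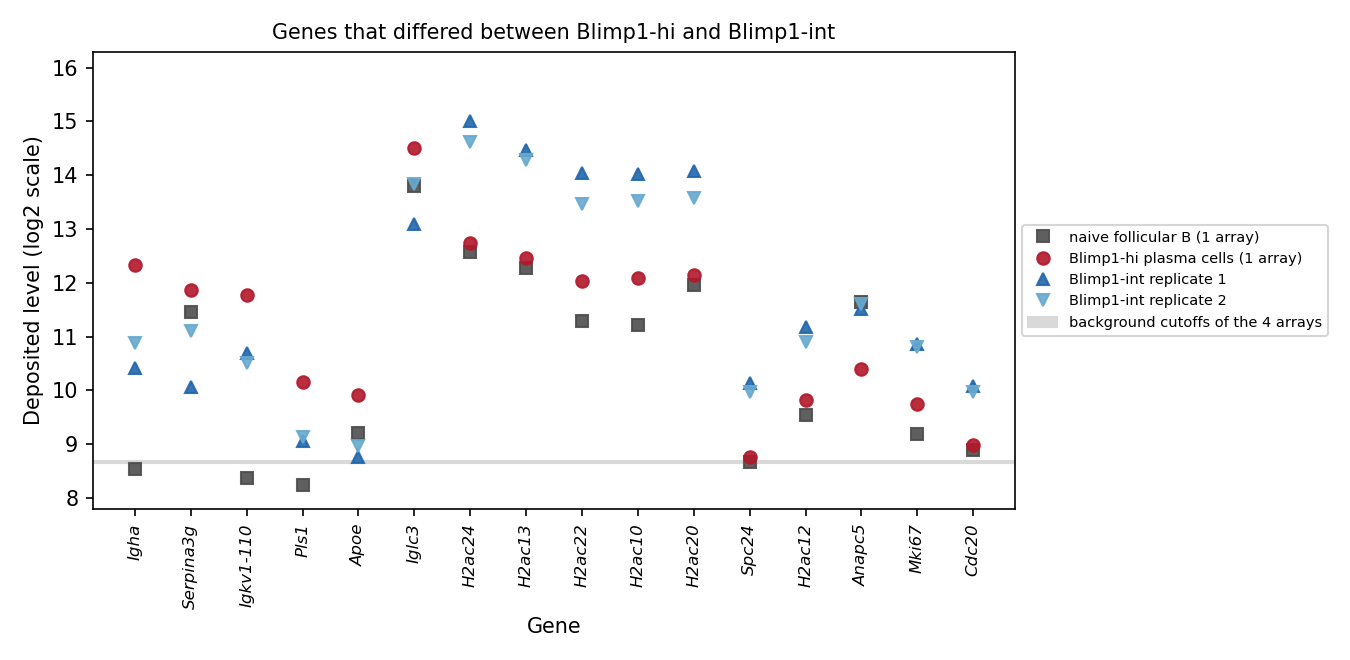
Deposited levels on the log2 scale (vertical axis) on each array of the genes with the largest called differences between Blimp1-hi and Blimp1-int (horizontal axis); each symbol is 1 array and the grey band spans the background cutoffs. From H2ac24 to Cdc20 both Blimp1-int replicates lie above the Blimp1-hi array, and the H2ac24 level of Blimp1-hi (12.73) is near that of naive B cells (12.57).

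Higher in Blimp1-hi were Igha (12.33 against 10.41 and 10.88, difference 1.68, SE 0.15), Serpina3g (1.29, SE 0.27), Igkv1-110 (1.18), the actin-bundling gene Pls1 (1.05), Apoe (1.05) and Iglc3, a lambda light chain constant region (1.04, SE 0.21). The remaining call, the mitochondrial gene ND5 (1.01, SE 0.13), was above background on part of the arrays only, and a second ND5 probe, kept apart, differed by 0.35 (adjusted p = 0.104). Apoe is on the list of macrophage markers, where it was the called one of 2 tested members, and its level in Blimp1-hi was 9.91 against 9.22 in naive cells. Without Blimp1-int replicate 1 the difference of Apoe was 0.94. Iglc3 and Serpina3g differed between the Blimp1-int replicates themselves (13.10 and 13.84, 10.06 and 11.10), and without replicate 1 their differences were 0.67 and 0.77, under 2-fold. The Serpina3g call also ended with intensity-trend and robust moderation (adjusted p = 0.615). The immunoglobulin list had 1 of 10 members called, with camera adjusted p = 0.0137 (adjusted p = 0.695 with an estimated correlation), a call that ended with each probe tested (0.0953). Several metabolic lists lay lower in Blimp1-hi as lists, with no single member called: glycolysis (median -0.68, camera adjusted p = 0.000202, Gapdh -0.86, Ldha -0.78), cholesterol synthesis (median -0.39, 0.000968, Fdps -0.66, Lss -0.44), oxidative phosphorylation (median -0.25, 0.000614, Uqcrc1 -0.58, Cycs -0.54) and ribosomal proteins (median -0.41, 2.63e-08, Rpl13 -0.92, Rpl27 -0.63). The ribosomal protein call ended without the immunoglobulin probes (adjusted p = 0.215), and for each of these lists the adjusted p was 0.695 with an estimated correlation. Among matched random lists the medians lay at percentile 0 for glycolysis and 0.04 for cholesterol synthesis, but at 5.38 for oxidative phosphorylation and 4.66 for ribosomal proteins, inside the central 95%. The secretory list passed with a median of -0.13 (0.0384, Cope -0.75, Ssr4 -0.52) and the immediate early list with a median of 0.16 (0.042, Junb 0.56, Egr2 0.29), and both had adjusted p = 0.695 with an estimated correlation. Egr2 was below background in Blimp1-int, so that its difference is not exact. The secretory call ended under cyclic loess (0.116), with the mean of probes (0.131) and without the immunoglobulin probes (0.365), and its median lay at percentile 53.6. The immediate early call ended under cyclic loess (0.0626), with the mean of probes (0.0508), with each probe tested (0.178) and without the immunoglobulin probes (0.0762). The lists of plasma cell and B cell identity showed no call between the populations: Xbp1 differed by -0.41, Zbtb20 by 0.29, Klf2 by -0.42, Cd55 by 0.45, H2-DMb2 by -0.26, Edem2 by -0.52, Sel1l by 0.34 and Sdc1 by 0.27. Median, mean and camera direction differed in sign for the pro-survival BCL-2 (median -0.12, mean 0.11, up), autophagy (-0.01, 0.04, up), interferon (-0.03, -0.01, up), plasma cell transcription factor (0.08, -0.01, up) and B cell transcription factor lists (0.02, -0.02, up), none of which passed. No member was called among the remaining lists, where the larger differences were those of Uggt1 (-0.48), Ganab (-0.26), Ccng1 (-0.29), Irf9 (-0.18), Sqstm1 (0.25), Aars (0.15), Birc2 (-0.12), Hba-a1 (-0.22) and Pecam1 (0.06). Hba-a1 was below background in both populations.

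The study used the arrays in work on plasma cell survival, so the BCL-2 family and the BAFF and APRIL system were examined in every group. Bcl2a1b, a pro-survival member of the A1 cluster, fell from 11.70 in naive cells to 9.62 in Blimp1-hi (-2.08, SE 0.14, adjusted p = 6.81e-08) and to 9.69 and 9.93 in Blimp1-int (-1.89, SE 0.12). Bcl2a1d fell as well (-1.65 and -1.46). The A1 genes are near-identical copies, so that these values are uncertain as separate genes, and Bcl2a1a lay near background on all arrays (8.64 to 8.79). Bcl2 lay at 8.90 in naive cells, 9.29 in Blimp1-hi, and 8.50 and 8.64 in Blimp1-int. The difference between Blimp1-hi and Blimp1-int was 0.72 (SE 0.11, adjusted p = 0.0011), at least 1.52-fold and under the 2-fold threshold, and Bcl2 was not called in any comparison. Bcl2l2, which encodes BCL-W, had differences of 0.63 and 0.28 from naive cells and was not called. Of 5 tested pro-survival genes 2 fell in each comparison with naive cells and 0 between the plasma cell populations. In Blimp1-int versus naive this list did not pass camera (adjusted p = 0.165), but passed it with no filter (median -0.18, adjusted p = 0.00916). Bcl2l1 (8.14 to 8.45) and Bcl2a1c (8.13 to 8.23), the pro-apoptotic genes Bok, Pmaip1, Bmf and Bcl2l14, and Tnfrsf13b, Tnfsf13 and Tnfsf13b, which encode TACI, APRIL and BAFF, did not exceed background on any array. Mcl1 and Tnfrsf17, which encodes the APRIL receptor BCMA, have no probe named here and were not analysed here.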

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

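Of the tests in this part, those of the variable segments and of the histone and mitotic genes were chosen after the result was seen. Features outside the gene tests that lay above background on all 3 plasma cell arrays and at least 2-fold above the naive array, the control here, drew attention. The neomycin resistance probe lay at 8.40 in naive cells, 11.20 in Blimp1-hi and at a mean of 11.14 in Blimp1-int; the deposited values differ by 2.76 on average, but the naive one is below background, so plasma cells were at least 5.70-fold higher. The 3 probes of 18S ribosomal RNA were 3.09, 3.83 and 2.36 higher on average in plasma cells than in naive cells. A pair of probes identified by a bare number, which are not named here, differed by 2.45 and 1.10; the second was below background in naive cells and at least 2.13-fold higher.

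Transcripts of H2A histone and cell cycle genes were mostly lower in Blimp1-hi than in Blimp1-int. Of 9 tested H2A genes 6 were called lower, with a median of -1.69 over all 9 and differences from -2.08 to 0.67. Their near-identical sequences make them uncertain as separate genes. Of 14 cell cycle genes 3 were called lower, with a median of -0.67 over all 14 (camera adjusted p = 0.695 with an estimated correlation). The calls of Cenpa and Cdc20 ended under alternatives. Replication-dependent histone messages lack a poly(A) tail, so more untailed RNA amplified from Blimp1-int could raise them. The 18S probes, also untailed, were not lower in Blimp1-hi (median difference 0.37, limma adjusted p between 0.065 and 0.43). On the plasma cell arrays they lie above the 99th percentile (11.49), where differences can be compressed. A 28S ribosomal RNA probe was below background on all arrays. These probes therefore do not decide on that explanation, and they do not cover the mitotic genes. Equally bright genes did not move alike: the cell cycle median lay at percentile 0 of matched random lists. Lists matched to the H2A genes, which were picked for being low, had medians with a 2.5 percentile of -0.45. Neither comparison can decide on an overall shift of the Blimp1-hi array, because the normalization had already evened out the arrays. The normalization itself holds the level of most genes, and the other scalings decide nothing, as they moved the median of all genes by only 0.036 and 0.016 (median of the called genes -1.55 or lower). Untested and open are a sampling difference of the single Blimp1-hi pool and a smaller share of dividing cells in Blimp1-hi.

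Probes of immunoglobulin variable segments differed between Blimp1-hi and Blimp1-int: of 197 tested, 61 were called higher in Blimp1-hi and 0 lower, 187 had a positive difference, and the median was 0.84. Variation between pools stays open, because Blimp1-hi has 1 array: 56 probes were at least 2-fold higher in Blimp1-hi than on both Blimp1-int arrays and 0 were so on either Blimp1-int array against the others. A higher total of immunoglobulin transcripts could not be settled by the constant region and J chain probes: the 4 below the arrays' 99th percentile had a median difference of 0.43, just over the bound of 50% of the variable segment median that would have argued against it, with a range from -0.15 to 1.68. A looser limit on brightness, under which 10 probes entered with a median of 0.18, would have fallen under that bound, so the outcome depends on that limit. A different repertoire or class makeup of the Blimp1-hi cells, and the chance makeup of its single pool, stay open as untested.

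Of 30 ribosomal protein genes 17 were called lower and 2 higher in Blimp1-hi (median -1.02, adjusted p = 0.691 with an estimated correlation), and 8 lower and 2 higher in Blimp1-int (median -0.51, adjusted p = 0.683 with an estimated correlation); the immunoglobulin probes that fill the top ranks of those arrays may push other bright probes down in the quantile normalization. The 309 probes recognized as immunoglobulin were then removed and the rest normalized again. The median of the list in Blimp1-hi versus naive went from -1.02 to -0.40. In Blimp1-int that median went to -0.24 and the list no longer passed camera (adjusted p = 0.0552). The list lay there at percentile 53.4 by the naive level and 4.23 by the mean level, inside the central 95% both times. Part of the difference therefore moved with the normalization. Whether the rest is free of it stays open, because immunoglobulin probes may remain among the unnamed ones. Whether all bright probes are compressed alike stays open: in Blimp1-hi the list lay at percentile 14.4 among random lists matched on the naive array's level but at percentile 0.21 among those matched on the mean of all arrays, and the first matching favours genes that happen to be bright on the naive array. A lower content of ribosomal protein messages in plasma cells cannot be told apart from this effect for the part that was left.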

How the results depend on the processing

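The normalization without immunoglobulin probes was chosen after the data were seen; the other alternatives were planned. No call of a named gene or list test reversed its direction under any alternative run, and 2 values of named genes that were not called changed sign. The balance of counts higher and lower did change. Without the immunoglobulin probes it went from 118 and 203 to 136 and 133 in Blimp1-hi versus naive. Under cyclic loess it went from 157 and 152 to 152 and 199 in Blimp1-int versus naive. With each probe tested it went from 7 and 11 to 87 and 28 in Blimp1-hi versus Blimp1-int. Of those 87 probes, 61 were immunoglobulin variable segments, a class with 0 called lower. Counts stayed within 1.5 times of the reported ones under 75th percentile scaling, cyclic loess, no filter, a looser background filter, a filter on at least 2 arrays, the mean of a gene's probes, trend and robust moderation, the fit of only the arrays compared, the 3 plasma cell arrays as 1 group, and an adjusted p under 0.01. With the adjusted p alone the counts higher and lower were 576 and 806 in Blimp1-hi versus naive, 744 and 778 in Blimp1-int versus naive, 81 and 263 in Blimp1-hi versus Blimp1-int, and 504 and 666 in both plasma cell populations. With a fold of at least 1.5 they were 303 and 446, 358 and 367, 31 and 63, and 247 and 329. With each probe tested, named or not, they were 568 and 587, 585 and 534, 87 and 28, and 460 and 467, since 8904 probes entered in place of 2625 genes. Without the immunoglobulin probes 133 genes were called lower in Blimp1-hi versus naive in place of 203, and of the 321 genes called in either direction 242 remained; the other counts stayed within 1.5 times. Over 2084 values of named genes under alternatives, 21 lost and 5 gained a call, and over 478 list tests 38 lost and 6 gained one, 26 of the losses with an estimated correlation. Leaving out either Blimp1-int replicate leaves no residual degree of freedom and so no test. It cannot change the differences in Blimp1-hi versus naive, which use neither replicate. Without replicate 1 or replicate 2, the genes past 2-fold numbered 289 and 339 in Blimp1-int versus naive (309 with both), 13 and 23 in Blimp1-hi versus Blimp1-int (18), and 321 each in Blimp1-hi versus naive. Not run were normexp with an offset of 50 and no background correction, which need the raw signals, and the slide as a block, for which no slide is given here; the authors' values are the reported ones. The detection p-value filters were replaced by the background cutoffs. Signal over background limits the dim genes: about 14% to 15% of probes exceeded background on each array, and a gene near the cutoff has only a bound. No paired analysis was possible because the groups share no replicate numbers from the labels.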

Other observations

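Immunoglobulin variable segments rose together in plasma cells. The 289 probes named by their identifiers were kept apart from the gene tests, while Igkv1-110, named by its gene number, is in those tests. Of the 289 probes, 197 exceeded background on at least 1 array. In the limma fit over all probes 168 of these were called higher and 0 lower in Blimp1-hi than in naive B cells, with a median difference of 3.21 on the log2 scale, and 154 higher and 0 lower in Blimp1-int, with a median of 2.18. On the naive array 122 of the 197 were below background, and with these at their bound the medians were 3.06 and 1.92. The medians of kappa and heavy chain segments, not tested against each other, were at the same bound 3.56 over 102 kappa probes (33 below background in naive cells) and 2.27 over 93 heavy chain probes (89 below) in Blimp1-hi, and 2.44 and 1.51 in Blimp1-int. Segments of 1 family share sequence, so that these probes do not count separate segments.

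Mitochondrially encoded transcripts differed in how far they changed between naive and plasma cells. COXIII fell from 15.87 to 14.19 in Blimp1-hi and to 13.99 and 14.10 in Blimp1-int, and ND1 from 15.13 to 13.33, 13.06 and 13.02. COXII lay at 13.68, 13.82, 13.63 and 13.43 on the naive, Blimp1-hi and Blimp1-int arrays, and ATP8 at 12.83, 12.86, 12.40 and 12.30. COXI and ND5 were lower in Blimp1-hi as well (-1.05 and -1.13), while ND4L, below background in naive cells, was at least 1.82-fold higher in Blimp1-hi. The brightest of these lie near the top of the scale, where the immunoglobulin probes may push other bright probes down in the quantile normalization. That effect was not examined for these probes.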
